A study of Mus musculus with 47 samples.

How the data were processed

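Poly-A selected, stranded RNA sequencing was available for 47 libraries of mouse cells in 3 tables of FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library), one for undifferentiated cells and days 1 and 2 (15 libraries), one for days 3.5 to 7.5 (28 libraries) and one for the Nkx2.2 arm (4 libraries). The authors name bcl2fastq 1.8.3, CASAVA, TopHat2 2.0.4, HTSeq 0.6.1, Cufflinks 2.1.1 and limma with the genome build GRCm38 (mm10); which of them made the deposited FPKM values, and from which annotation, is not stated. Raw reads and counts were not used here, and 3 columns that belong to none of the 47 libraries were not used either. Repeated identifiers were reduced to one, which left 38347 genes in each of the first 2 tables and 37514 in the third, and 95.2% and 86.8% of these were found in GENCODE M21, which gave positions, lengths and gene types. Values of exactly 0 may be failed estimates, since 37 to 182 genes per library were listed at 0 while another library of the group was at FPKM 5 or more; Gapdh, for instance, was listed at 0 in 3 libraries. FPKM gives no counts, so depth was estimated from the spacing of low values of genes with a single transcript, and intervals from counts are not given; the range of depth stands with the results.

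Each table was analysed on its own in R 4.3.3 with limma 3.58.1 and data.table (version 1.17.8), and figures were drawn in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Genes at FPKM 1 or more in at least 2 libraries were kept (16465 up to day 2 and 17124 later), and log2(FPKM + 1) was fitted with one mean per group over all libraries of a table. Contrasts were tested with empirical Bayes moderation with a mean-variance trend, two-sided, and adjusted by the Benjamini-Hochberg method over all genes; genes with adjusted p under 0.05 were called. The added 1 understates changes of genes at low FPKM, and no fold is a bound where one group is near 0. Foxa2-/- cells were compared with WT cells at each of 8 times. Day 2 was compared with undifferentiated cells and day 7.5 with day 3.5 within each genotype. The difference between genotypes in these changes was tested as an interaction. This removes a difference between the lines that is constant in time on the log2(FPKM + 1) scale. For a gene near 0 at the earlier or later time, the added 1 shrinks a constant fold difference there and can leave an interaction. The labels give replicate numbers but no shared origin, and the samples were not treated as paired.

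The 35 gene lists, with 480 genes, the comparisons, the main settings and a first set of alternatives were fixed before the data were examined. Lists with at least 3 measured members were tested with camera at a preset correlation between genes of 0.01 (the values given as camera adjusted p) and also with an estimated correlation and with fry, and adjusted over the lists of a comparison. Of 164 list calls 20 held with an estimated correlation, among them those of the floor plate list from day 3.5 to day 7.5 and of the TGF-beta list from day 3.5 to day 7.5. Every list whose direction is given for a comparison of Foxa2-/- and WT cells kept the sign of its median under the 3 other scalings. In the Nkx2.2 arm, with 1 library per group, no test was made; a test of genotype over both days, with the difference between the days as the error, was left out. Genes at FPKM 1 or more in at least 1 library were kept (15141), and a list's median log2 difference was placed among the medians of 10000 random lists of the same size, drawn from 20 bins of mean expression. FPKM levels are not compared between tables, except for the levels that a share of undifferentiated cells would give.

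Genes were named by a fixed rule: Foxa2 and Nkx2-2 in every sample; for each comparison of genotypes and each interaction the 8 largest rises and falls among called genes with a mean FPKM of at least 1 in one group and, for comparisons of genotypes, no overlap between replicates (which 10% of genes show by chance with 3 against 3); up to 4 called genes per direction of each list; members of the floor plate, p3, somatic and visceral motor neuron, SHH target and line lists; and in the Nkx2.2 arm the 8 highest and lowest differences per day among genes at FPKM 5 or more, and list members. With 3 against 2 libraries, as up to day 2 and on days 6.5 and 7.5, more genes show no overlap by chance. From the genes this rule admits, small RNAs and genes with zeros of the failed kind were skipped and the next protein-coding genes taken in their place (Igfbp5 in the day 2 interaction is one), a choice made after the values were seen. Some genes that the rule admits are not reported here. The genes printed are those whose call held when each library was left out, except Pax6 on day 3.5, Mki67 on days 6.5 and 7.5 and over time in the mutant, and Olig2 on day 7.5.

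The alternatives were a pseudocount of 0.1, no filter, median-of-ratios factors, quantile normalization, no variance trend, a replicate block, only the groups compared in the fit, and each library left out in turn. Added after seeing the data were isolated zeros as missing, removal of each library's loess trend (span 0.5) with transcript length, limma's array weights, and, for comparisons with day 2, leaving out both mutant libraries with a length slope below -0.1. Where a left-out library leaves 1 in a group, that library is taken to vary like the other groups. The procedure was tested on simulated libraries, with changes added to 200 genes at FPKM 5 or more. Each simulated value was the group mean plus normal noise, with a single spread per gene for all groups. This is the noise that the fit assumes, so the test does not cover libraries or groups that vary more than others. Of changes of 1 on the log2 scale 47% were recovered in undifferentiated cells, 42% on day 2, 68% on day 5.5 and 63% on day 7.5, and of changes of 2 between 87% and 93%, with 4, 9, 11 and 17 false calls.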

Results

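RNA was sequenced from 47 libraries of mouse embryonic stem (ES) cells and of cells that were differentiated from them as a monolayer in N2B27 medium with retinoic acid and SAG. Retinoic acid promotes neural fates of hindbrain and spinal cord character, and SAG is an agonist of Smoothened that activates the Sonic hedgehog (SHH) pathway, which promotes ventral fates. The series compares wild-type (WT) cells with cells that lack Foxa2, a forkhead transcription factor of the floor plate and notochord. A smaller arm compares WT cells with cells that lack Nkx2.2, a homeodomain factor of the p3 progenitors next to the floor plate. Undifferentiated cells and days 1 and 2 were each represented by 2 WT and 3 Foxa2-/- libraries. Days 3.5, 4.5 and 5.5 each had 3 libraries of both genotypes, and days 6.5 and 7.5 had 3 WT and 2 Foxa2-/- libraries. From day 3.5 on, the cells were sorted for the progenitor surface protein prominin and the positive cells were sequenced. The Nkx2.2 arm had 1 mutant and 1 WT library at each of days 3.5 and 5.5, and these cells received SAG for the first 3.5 days only. Cells collected after day 3.5 received retinoic acid for the first 3.5 days only, in both arms. SAG was given up to the day of collection in the comparison of WT and Foxa2-/- cells. The tables give FPKM, so depth was estimated from the steps between low values: 35500000 to 41600000 fragments per library up to day 2, 14300000 to 33100000 from day 3.5 on, and 10400000 to 12800000 in the Nkx2.2 arm. Libraries of one group correlated across genes with r between 0.917 and 0.971. The undifferentiated Foxa2-/- replicate 3 carries a source name of neural progenitors although its stage reads undifferentiated, and it correlated with the other libraries of its group at 0.956 or more. Foxa2-/- replicates 1 and 3 of day 2 stood apart, with fewer reads on long transcripts (slopes of -0.372 and -0.145 log2 units per doubling of length, against 0.132 in replicate 2). They also had 169295 and 54105 FPKM of the small RNA Gm26377 against 30435. Foxa2-/- replicate 1 of day 3.5 and replicate 2 of day 6.5 had slopes of -0.127 and -0.107, against 0.048 in replicate 3 of day 3.5 and in replicate 1 of day 6.5. WT and Foxa2-/- cells also carry different line labels (E14.5 and C57BL/6), so each difference between them is one between lines as well as genotypes. The replicates are not said to be separate cultures. The p-values measure only the spread between libraries within groups, pooled over all groups of a table, so genes of a group that varies more than the others can be called too easily.

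Foxa2, the targeted gene (ENSMUSG00000037025, GRCm38 chromosome 2, 148042877 to 148046969), was switched on during WT differentiation and stayed near 0 in the mutant. In WT cells it stood at 0.629 ± 0.0571 FPKM undifferentiated (SD, n = 2), 3.59 ± 0.315 on day 1, 33.7 ± 11.6 on day 2, 46 ± 10.4 on day 3.5 (n = 3), 64.8 ± 19.7 on day 4.5, 80.1 ± 17.4 on day 5.5, 74.2 ± 8.96 on day 6.5 and 79.4 ± 12.4 on day 7.5. In Foxa2-/- cells its means were 0.00454 ± 0.00787 FPKM undifferentiated (n = 3), 0.0284 ± 0.0247 on day 1, 0.0123 ± 0.0212 on day 2, 0.0606 ± 0.0335 on day 3.5, 0.144 ± 0.107 on day 4.5, 0.0673 ± 0.0957 on day 5.5, 0.01 ± 0.0142 on day 6.5 (n = 2) and 0.0787 ± 0.0266 on day 7.5. The difference was not called in undifferentiated cells (log2 fold change -0.70, adjusted p = 0.159) and was called at every later time, from -2.16 on day 1 to -5.06 on day 2 and between -5.45 and -6.23 from day 3.5 on. Nkx2-2, which encodes Nkx2.2 (chromosome 2, 147177546 to 147194243), was below 1 FPKM up to day 2 in both genotypes (0.796 ± 0.36 in Foxa2-/- and 0.924 ± 0.67 in WT cells on day 2). On day 3.5 it stood at 14.3 ± 5.1 FPKM in Foxa2-/- and 9.1 ± 1.14 in WT cells, a difference that was not called (adjusted p = 0.417). It was higher in the mutant from day 4.5 on, at 44.4 ± 2.01 against 11 ± 3.16 FPKM on day 4.5, 58.1 ± 7.46 against 15.1 ± 4.23 on day 5.5, 46.5 ± 10.4 against 12.9 ± 5.77 on day 6.5 and 49.8 ± 10 against 6.45 ± 1.28 on day 7.5. Its log2 fold changes were 1.95, 1.91, 1.85 and 2.77, and the call on day 6.5 ended when only the groups compared were in the fit.

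**Figure D1:**
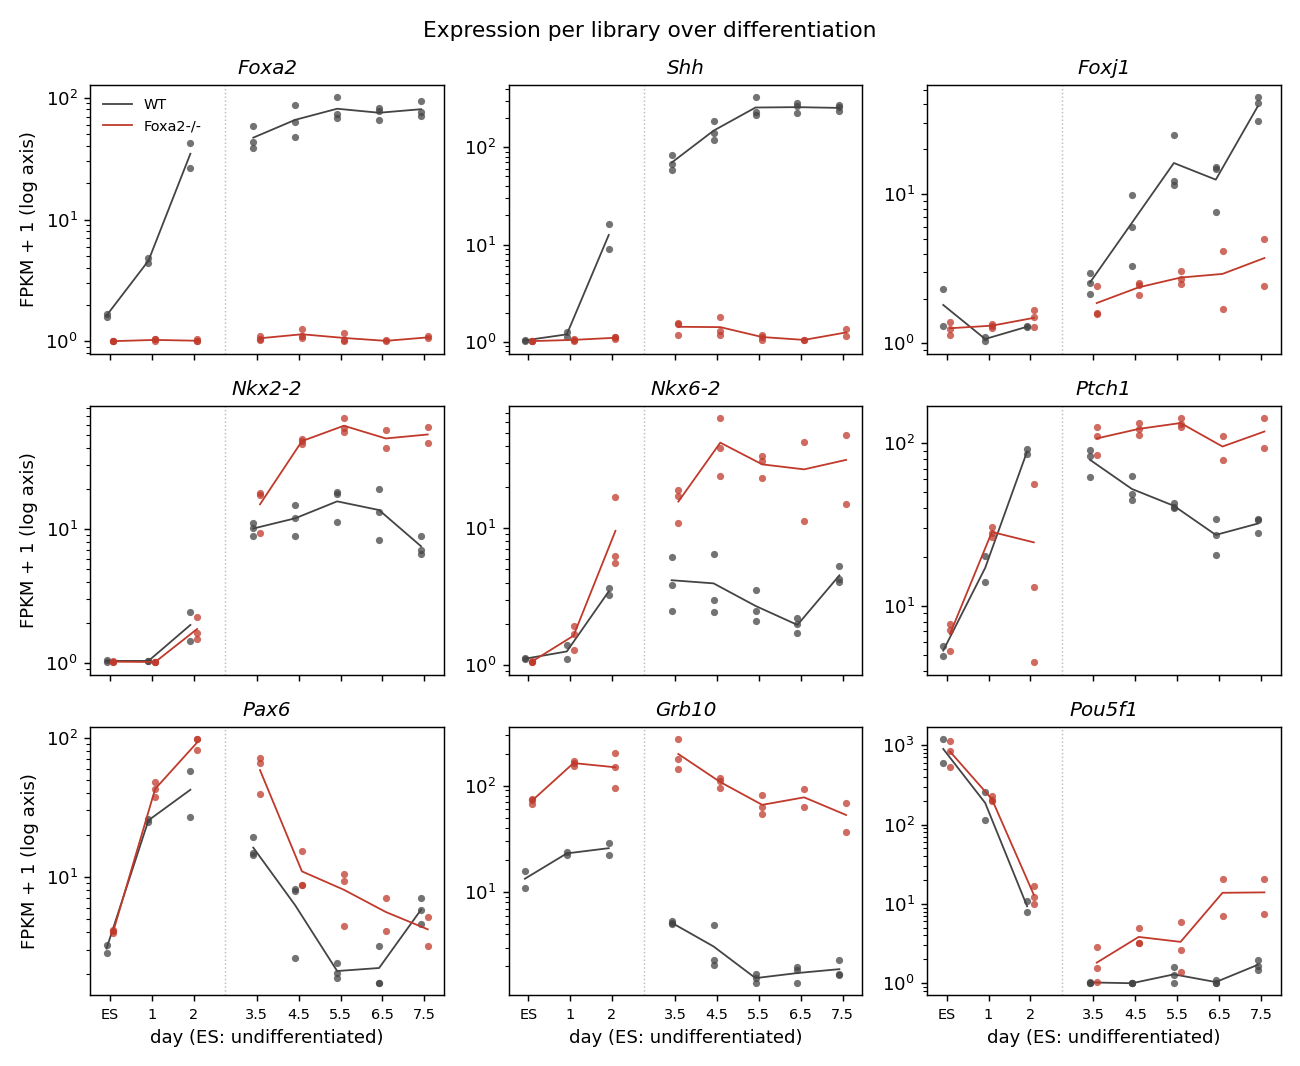
FPKM + 1 (log axis) of 9 genes in every library (points) and group means (lines) of WT and Foxa2-/- cells against the day of differentiation, with a dotted line between the table of days 0 to 2 and that of later days. Foxa2 and Shh rise in WT cells alone and reach 79.4 ± 12.4 and 252 ± 19.2 FPKM on day 7.5, while Nkx2-2 reaches 49.8 ± 10 FPKM in Foxa2-/- cells.

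Undifferentiated Foxa2-/- and WT cells were compared to find differences that precede any differentiation. Grb10, an imprinted adaptor protein of insulin receptor signalling (chromosome 11, 11930508 to 12038683), was the gene of the fixed lists with the largest rise, by 2.45 on the log2 scale (70.5 ± 3.9 FPKM in Foxa2-/- and 12.3 ± 3.58 in WT cells, SD, n = 3 and 2). Arhgap6 fell by 3.11 (0.61 ± 0.0858 against 13 ± 2.74 FPKM). The Y-linked histone demethylase gene Kdm5d fell by 1.24 (0.46 ± 0.0159 against 2.44 ± 0.211 FPKM). Of the 5 tested sex-linked and strain genes of the line list 1 fell (3 adjusted over the list alone). Camera gave the list adjusted p = 1.73e-06, and adjusted p = 0.0883 with an estimated correlation. Genes of the 2-cell-like state, a rare state of ES cell cultures marked by the Zscan4 family, were lower: 4 of 8 fell (8 adjusted over the list alone). As a list they had a camera adjusted p of 1.73e-24, and adjusted p = 0.00796 with an estimated correlation. In all, 62 of 16465 genes were called, 13 higher and 49 lower in the mutant, and 833 had an unadjusted p under 0.05. The count was 23 without WT replicate 1, 28 without Foxa2-/- replicate 1, 29 without Foxa2-/- replicate 3 and 24 with only the groups compared, where the call of Grb10 ended. It was 165 with no filter, 21 with a replicate block, 207 with isolated zeros as missing and 1.4e+02 (rounded) with array weights. With isolated zeros as missing or the length trend removed 44.9% and 42.9% of the called genes were higher in place of 21%.

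Day 1 gives the first step of differentiation, when WT cells had begun to express Foxa2. In the neural list 4 of 17 genes rose (12 adjusted over the list alone), among them Sox1, a marker of early neural cells (13.1 ± 0.137 FPKM in Foxa2-/- and 6.64 ± 0.795 in WT cells, SD, n = 3 and 2). The camera test gave adjusted p = 2.96e-06, and adjusted p = 0.0484 with an estimated correlation. Of 11 endoderm markers 4 rose (9 adjusted over the list alone). Together they had a camera adjusted p of 3.18e-06, and adjusted p = 0.152 with an estimated correlation. Of the 7 SHH target genes 3 rose, among them Mycn, a driver of progenitor growth (16.1 ± 1.89 against 5.54 ± 0.176 FPKM). For this list camera gave adjusted p = 0.00121, and adjusted p = 0.162 with an estimated correlation. Among genes of the 2-cell-like state 6 of 8 fell (8 adjusted over the list alone), such as Zscan4c (9.91 ± 0.911 against 30.3 ± 0.848 FPKM). Tested as a list, they had camera adjusted p = 5.03e-14, and adjusted p = 0.0484 with an estimated correlation. Grb10 rose by 2.82 (162 ± 8.63 against 22.1 ± 1.05 FPKM) and Arhgap6 fell by 3.17 (0.713 ± 0.0655 against 14.4 ± 0.821 FPKM). Single genes with large rises were Acta2, which encodes smooth muscle actin, by 3.59 (56.1 ± 2.67 against 3.81 ± 1.03 FPKM), the transgelin gene Tagln by 3.11 (214 ± 7.42 against 24.9 ± 9.99 FPKM) and the calponin gene Cnn1 by 2.81 (18.1 ± 2.47 against 1.75 ± 0.686 FPKM). The cardiac actin gene Actc1 and the myosin light chain gene Myl9 rose by 2.80 and 2.60. There were 309 called genes, 197 higher and 112 lower. Of these, 45 of the 185 higher genes tested in both tables were also higher on day 2, where 3.1 would be shared between independent lists. Both days compare the same lines in the same fit, so a constant line difference or the shared spread can also give this overlap. The count was 62 without WT replicate 1 and 52.1%, 43.4% and 39.2% of its value without Foxa2-/- replicates 1, 2 and 3. It was 150 with only the groups compared, where the call of Sox1 ended, 132 with a replicate block, 5.2e+02 (rounded) with no filter, 510 with isolated zeros as missing and 813 with array weights. The excess of higher genes depended on the scaling. With median-of-ratios factors 51.1% were higher in place of 63.8% (median shift of all genes -0.132), and with quantile normalization 155 were higher and 198 lower (shift -0.161). The higher share was 51.6% with the length trend removed (shift -0.169) and 50.4% with no filter.

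Day 2 is the last day before sorting and the time at which WT cells first expressed Foxa2 strongly. Foxa1, a floor plate gene and close relative of Foxa2, fell by 2.52 (0.502 ± 0.153 FPKM in Foxa2-/- and 7.65 ± 1.28 in WT cells, SD, n = 3 and 2). Shh, the signal secreted by the floor plate (chromosome 5, 28456815 to 28467256), fell by 3.45 (0.102 ± 0.0287 against 11.5 ± 5 FPKM). The axon guidance genes Ntn1 (netrin 1) and Slit2 fell by 1.78 (18.8 ± 0.743 against 67.2 ± 11 FPKM) and 2.46 (2.6 ± 1.66 against 17.8 ± 3.92 FPKM). Of 13 floor plate genes tested 9 fell (10 adjusted over the list alone). In the camera test the list had adjusted p = 2.00e-09, and adjusted p = 0.0679 with an estimated correlation. The matrix gene Vtn (vitronectin) fell by 3.80 (0.165 ± 0.0969 against 16.2 ± 8.2 FPKM) and the growth factor-binding gene Igfbp5 by 3.46 (12.8 ± 2.75 against 152 ± 51.9 FPKM). Arhgap6 fell by 3.90 (0.355 ± 0.146 against 19.2 ± 1.26 FPKM) and the epithelial cadherin gene Cdh1 by 2.42 (8.32 ± 1.69 against 48.8 ± 10.4 FPKM). Epithelial genes fell in 5 of 11 cases (8 adjusted over the list alone). Tested with camera, these genes had adjusted p = 5.75e-07, and adjusted p = 0.161 with an estimated correlation. Higher in the mutant were the signalling gene Wnt7a by 2.85 (30.8 ± 16.1 against 3.07 ± 0.889 FPKM) and Grb10 by 2.47 (148 ± 54 against 24.8 ± 4.77 FPKM). Fabp7, which marks radial glial progenitors, rose by 1.52 (14.8 ± 3.19 against 4.44 ± 0.367 FPKM), and the homeobox gene Irx5 rose to 7.83 ± 0.643 against 2.85 ± 0.364 FPKM. Neural progenitor genes rose in 6 of 17 cases (7 adjusted over the list alone). This list had a camera adjusted p of 3.69e-05, and adjusted p = 0.0679 with an estimated correlation. Markers of intermediate and dorsal progenitors rose in 5 of 9 cases. These genes had a camera adjusted p of 0.04, and adjusted p = 0.446 with an estimated correlation. Genes of the 2-cell-like state fell in 6 of 8 cases (8 adjusted over the list alone). By camera the list had adjusted p = 1.96e-08, and adjusted p = 0.0679 with an estimated correlation. In all, 875 genes were called, 263 higher and 612 lower. Without both libraries with a steep length trend 248 were called, 62 higher and 186 lower, and Fabp7 was not among them. The count was 258 and 278 without WT replicates 1 and 2 and 61.8%, 690.2% and 41.7% of its value without Foxa2-/- replicates 1, 2 and 3. The higher share moved from 30.1% to 44.4% with quantile normalization (280 higher and 351 lower, median shift 0.126) and to 44.3% with the length trend removed (357 and 448). With a replicate block 384 were called (22.7% higher), with isolated zeros as missing 1316 (35.5%) and with array weights 10450 (49.2%). With only the groups compared 32 genes were called, with Foxa2, Foxa1, Shh and Arhgap6 among them and the calls of the other genes named for this day ended.

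On day 3.5, the first day of sorted prominin-positive cells, most floor plate genes were lower in the mutant. Shh fell by 5.60 (0.428 ± 0.214 FPKM in Foxa2-/- and 68.4 ± 11.8 in WT cells, SD, n = 3 each), and Slit2 by 3.66. The secreted F-spondin gene Spon1 fell by 3.12 (5.73 ± 1.16 against 57.4 ± 7.58 FPKM) and Ntn1 by 2.43 (29.9 ± 4.52 against 166 ± 32.7 FPKM). The transcription factor genes Foxa1 and Ferd3l fell by 3.33 and 3.06. Of 17 floor plate genes 12 fell (16 adjusted over the list alone). Their camera adjusted p was 8.33e-38, and adjusted p = 0.00128 with an estimated correlation. The notochord list fell in 2 of 7 genes, Shh and the BMP antagonist gene Nog (0.91 ± 0.308 against 6.57 ± 1.84 FPKM). Camera gave the list adjusted p = 1.40e-04, and adjusted p = 0.0314 with an estimated correlation. It shares Shh, Foxj1 and Sox9 with other lists. TGF-beta pathway genes fell in 3 of 9 cases (6 adjusted over the list alone), such as the latency gene Ltbp1 (4.69 ± 0.891 against 16.4 ± 0.528 FPKM) and the ligand gene Tgfb3 (1.24 ± 0.348 against 3.29 ± 0.58 FPKM). As a list they had a camera adjusted p of 2.19e-04, and adjusted p = 0.0226 with an estimated correlation. Vtn fell by 5.70 (1.38 ± 0.666 against 124 ± 43.3 FPKM), and Arhgap6 by 4.41. The Notch effector gene Hey1 fell by 2.08 (10.7 ± 0.598 against 48.5 ± 6.17 FPKM) and the semaphorin co-receptor gene Nrp1 by 2.54 (1.64 ± 0.475 against 14.2 ± 0.81 FPKM). Cdh1 fell to 1.56 ± 0.773 against 10.7 ± 0.78 FPKM, one of 3 of 8 epithelial genes called (7 adjusted over the list alone). The camera test gave adjusted p = 1.27e-06, and adjusted p = 0.0396 with an estimated correlation. Higher in the mutant were Pax6, a homeobox gene of progenitors outside the floor plate and p3 domain, by 1.82 (57.5 ± 16.9 against 15.2 ± 2.8 FPKM, adjusted p = 0.0119), and Grb10 by 5.21 (197 ± 68.2 against 4.15 ± 0.156 FPKM). The imprinted zinc-finger gene Plagl1 rose by 1.84 (130.2 ± 42 against 34.5 ± 3.73 FPKM) and the glial glutamate transporter gene Slc1a3 by 1.57 (32.1 ± 11.3 against 9.73 ± 0.617 FPKM). Of 579 called genes 116 were higher and 463 lower. Of these, 337 of the 400 lower genes tested in both tables were lower on day 4.5 too and 284 on day 7.5, where independent lists would share 21 and 43.1. These days compare the same lines in the same fit. A constant line difference or the shared spread can therefore also give such overlaps. The count was 381, 374 and 341 without WT replicates 1, 2 and 3, with 12.3%, 12.6% and 14.7% higher. Without Foxa2-/- replicate 1 it was 444 (25% higher), with isolated zeros as missing 878 (28.9%) and with array weights 4907 (46.8%). The higher share moved from 20% to 32.6% with the length trend removed. The calls of Slc1a3 and Tgfb3 ended with only the groups compared. Pax6 lost its call without Foxa2-/- replicate 1 (1.66) or 2 (1.72) and without WT replicate 1 (1.76) or 3 (1.74), with adjusted p up to 0.062 over all its alternatives.

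On day 4.5 the p3 genes Nkx2-2, Nkx6-2 and Nkx2-9 and the SHH target gene Ptch1 were higher in the mutant, and the floor plate genes Shh and Corin were lower. Nkx6-2 and Nkx2-9, homeobox genes of ventral progenitors, rose by 3.44 (41.2 ± 20.1 FPKM in Foxa2-/- and 2.95 ± 2.18 in WT cells, SD, n = 3 each) and 2.42 (25.6 ± 7.32 against 4.64 ± 3.97 FPKM). With Nkx2-2 they were the 3 of 7 p3 genes called. Together they had a camera adjusted p of 0.00199, and adjusted p = 0.243 with an estimated correlation. Ptch1, the SHH receptor gene and a direct target of the pathway (chromosome 13, 63508328 to 63573598), rose by 1.24 (122 ± 10 against 51.4 ± 9.74 FPKM). Of 7 SHH targets 4 rose. For this list camera gave adjusted p = 2.07e-04, and adjusted p = 0.0876 with an estimated correlation. Gli2, which encodes a transcription factor that transmits the SHH signal, rose to 4.11 ± 1.65 against 1.09 ± 0.556 FPKM. Shh itself fell by 6.70 (0.417 ± 0.32 against 147 ± 34.8 FPKM) and the serine protease gene Corin by 4.42 (0.0885 ± 0.104 against 30.6 ± 31 FPKM). Floor plate genes fell in 14 of 17 cases (16 adjusted over the list alone). Tested as a list, they had camera adjusted p = 1.65e-35, and adjusted p = 0.00184 with an estimated correlation. Vtn, the secreted factor gene Metrnl and Kitl, which encodes the ligand of the receptor Kit, fell by 6.59, 5.05 and 5.05. Motile cilia genes fell in 5 of 16 cases (6 adjusted over the list alone). In the camera test the list had adjusted p = 0.00172, and adjusted p = 0.351 with an estimated correlation. In the TGF-beta list 6 of 9 genes fell, such as the receptor gene Tgfbr2 (0.9 ± 0.223 against 5.22 ± 2.98 FPKM). Tested with camera, these genes had adjusted p = 1.40e-05, and adjusted p = 0.00452 with an estimated correlation. The retinoic acid-degrading enzyme gene Cyp26b1 rose by 2.75 (7.05 ± 0.567 against 0.199 ± 0.119 FPKM), the homeobox gene Vax1 by 2.49, the calcium-binding gene S100g by 2.76, Grb10 by 5.24 and Plagl1 by 2.34. There were 1285 called genes, 289 higher and 996 lower. The count was 770 without WT replicate 1 and 2217 with array weights (31% higher), and the higher share moved from 22.5% to 36.4% with the length trend removed. With only the groups compared 580 genes were called and the calls of Nkx2-9, Gli2, S100g and Tgfbr2 ended.

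On day 5.5, in the middle of the sorted time course, Shh, Corin and Foxj1 were lower in the mutant, and Nkx2-2, Nkx6-2, Ptch1 and Gli1 were higher. Shh stood at 0.12 ± 0.067 FPKM in Foxa2-/- and 254 ± 61.9 in WT cells (SD, n = 3 each, log2 fold change -7.81, adjusted p = 5.14e-17). Corin fell by 5.93 (0.0196 ± 0.0213 against 72.1 ± 52.7 FPKM) and Vtn by 8.21 (1.1 ± 0.385 against 654 ± 297 FPKM). The cell adhesion gene Alcam and Kitl fell by 5.79 (0.946 ± 0.0804 against 108 ± 22.9 FPKM) and 5.96. Floor plate genes fell in 15 of 17 cases (16 adjusted over the list alone). This list had a camera adjusted p of 1.32e-30, and adjusted p = 0.00418 with an estimated correlation. Foxj1, the master regulator gene of motile cilia (chromosome 11, 116330704 to 116335399), fell by 2.46 (1.76 ± 0.288 against 15.2 ± 7.46 FPKM), and it is on the floor plate list as well. Motile cilia genes fell in 9 of 16 cases (11 adjusted over the list alone). These genes had a camera adjusted p of 2.64e-06, and adjusted p = 0.15 with an estimated correlation. Nkx6-2 rose by 3.46 (28.3 ± 5.22 against 1.7 ± 0.741 FPKM) and Nkx2-9 by 2.53 (9.65 ± 1.21 against 0.858 ± 0.337 FPKM), so that with Nkx2-2 3 of 7 p3 genes rose. By camera the list had adjusted p = 0.00446, and adjusted p = 0.298 with an estimated correlation. Tbx20, a gene of visceral motor neurons, rose by 1.63 (20.3 ± 1.01 against 6.27 ± 2.63 FPKM). SHH targets rose in 6 of 7 cases. Their camera adjusted p was 7.41e-05, and adjusted p = 0.0686 with an estimated correlation. Ptch1 rose by 1.69 (132 ± 9 against 40.3 ± 1.52 FPKM), the transcription factor gene Gli1 by 1.76 (7.62 ± 2.78 against 1.5 ± 0.503 FPKM) and the SHH-binding antagonist gene Hhip by 1.29 (11.6 ± 2.69 against 4.08 ± 0.419 FPKM). Cdon, which encodes a co-receptor that SHH signalling represses, fell by 2.63 (2.17 ± 0.703 against 18.7 ± 4.34 FPKM). TGF-beta genes fell in 6 of 9 cases (7 adjusted over the list alone), among them Tgfbr2 (0.728 ± 0.0208 against 9.39 ± 3.35 FPKM) and Tgfb2 (1.4 ± 0.0632 against 6.2 ± 1.86 FPKM). Camera gave the list adjusted p = 1.73e-04, and adjusted p = 0.0177 with an estimated correlation. The ligand gene Bmp7 and the co-receptor genes Nrp1 and Nrp2 fell by 2.58, 3.15 and 3.14. Of 21 imprinted genes 4 rose and 7 fell (camera adjusted p = 0.535). Grb10 rose by 5.39, and the growth factor gene Igf2 fell by 3.30 (3.91 ± 0.398 against 53.1 ± 26.6 FPKM) and Peg3 by 2.00. Cyp26b1 and Fam181a rose by 3.58 and 2.89. Of 2442 called genes 775 were higher and 1667 lower, and no left-out library moved the count by more than 1.5 times. With array weights 6267 were called, 41.7% of them higher in place of 31.7%. With the length trend removed 1396 were higher and 1304 lower (median shift 0.109).

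On day 6.5 there were 2 mutant libraries, and some genes differed widely between them. Mki67, the gene of the proliferation antigen Ki-67, rose by 1.18 (74.2 ± 39.3 FPKM in Foxa2-/- and 30.7 ± 8.76 in WT cells, SD, n = 2 and 3). The replication licensing genes Mcm3 and Mcm5 rose by 1.90 (77.3 ± 9.66 against 20.8 ± 7.72 FPKM) and 1.83, and the mitotic kinase gene Aurkb by 1.53 (71.3 ± 1.5 against 24.2 ± 2.99 FPKM). Of 25 cell cycle genes 24 rose. As a list they had a camera adjusted p of 1.75e-12, and adjusted p = 0.272 with an estimated correlation. Shh fell by 7.93 (0.0472 ± 0.00284 against 257 ± 32.4 FPKM), Alcam by 6.74 and Vtn by 7.64. Floor plate genes fell in 15 of 17 cases (16 adjusted over the list alone). The camera test gave adjusted p = 6.63e-24, and adjusted p = 0.0146 with an estimated correlation. Foxj1 fell to 1.93 ± 1.74 against 11.5 ± 4.32 FPKM. Of 16 motile cilia genes 11 fell and 1 rose. Together they had a camera adjusted p of 7.47e-06, and adjusted p = 0.246 with an estimated correlation. SHH targets rose in 6 of 7 cases (7 adjusted over the list alone), such as Ptch1 (94.7 ± 22.7 against 26.4 ± 6.9 FPKM) and Gli1 (4.46 ± 0.282 against 0.563 ± 0.346 FPKM). For this list camera gave adjusted p = 2.33e-04, and adjusted p = 0.126 with an estimated correlation. Of 7 p3 genes 3 rose and 1 fell (camera adjusted p = 0.133), with Nkx6-2 at 25.9 ± 22.1 against 0.962 ± 0.248 FPKM. In the TGF-beta list 7 of 9 genes fell. Tested as a list, they had camera adjusted p = 1.62e-04, and adjusted p = 0.0172 with an estimated correlation. S100g rose by 4.93 (42.2 ± 8.16 against 0.419 ± 0.243 FPKM) and Grb10 by 5.47. Pou5f1, a gene of pluripotent cells, rose by 3.53 (12.8 ± 9.68 against 0.0347 ± 0.0601 FPKM) and the apolipoprotein gene Apoe by 3.66 (42.8 ± 46.1 against 1.41 ± 0.826 FPKM). The epithelial genes Cldn6 and Epcam rose by 2.77 and 1.70. Of 11 naive pluripotency genes 5 rose. In the camera test the list had adjusted p = 0.00295, and adjusted p = 0.272 with an estimated correlation. There were 4264 called genes, 2220 higher and 2044 lower. The larger side depended on the scaling and on single libraries. With median-of-ratios factors 1834 were higher and 2255 lower, with quantile normalization 1953 and 2162, without WT replicate 2 46.2% were higher, and without Foxa2-/- replicates 1 and 2 60.2% and 49.5%. With array weights 2675 were called (49.9% higher). With only the groups compared 640 were called, 25.5% of them higher in place of 52.1%. The calls of Nkx2-2, Nkx6-2, Ptch1, Mki67, Mcm3, Mcm5, Apoe, Cldn6 and Foxj1 ended there. Mki67 lost its call without Foxa2-/- replicate 1 (0.62).

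On day 7.5, the last day, Shh, Corin and Foxj1 were lower in the mutant, and Nkx2-2, Nkx6-2 and Isl1 were higher. Corin stood at 0.113 ± 0.0475 FPKM in Foxa2-/- and 282 ± 42.6 in WT cells (SD, n = 2 and 3, log2 fold change -7.98). Vtn fell by 9.53, Shh by 7.66 (0.249 ± 0.138 against 252 ± 19.2 FPKM) and Alcam by 6.97. Ferd3l and Kitl fell by 6.74 and 6.63. Of 17 floor plate genes 16 fell. Tested with camera, these genes had adjusted p = 7.62e-25, and adjusted p = 0.0121 with an estimated correlation. Foxj1 (2.74 ± 1.85 against 37.9 ± 7.03 FPKM) and the ciliary tektin genes Tekt4 (0.0835 ± 0.0816 against 4.62 ± 0.57 FPKM) and Tekt1 (1.84 ± 0.199 against 8.84 ± 1.03 FPKM) were among 12 of 16 motile cilia genes that fell, with 1 that rose. This list had a camera adjusted p of 5.10e-08, and adjusted p = 0.134 with an estimated correlation. Nkx6-2 rose by 2.59 (30.6 ± 23.2 against 3.52 ± 0.693 FPKM) and Nkx2-9 by 2.01, 2 of the 3 of 7 p3 genes that rose (4 adjusted over the list alone). These genes had a camera adjusted p of 0.00477, and adjusted p = 0.288 with an estimated correlation. Isl1, a motor neuron gene, rose by 2.14 (15.6 ± 9.12 against 3.05 ± 2.79 FPKM) and Tbx20 by 2.02. Of 7 visceral motor neuron genes 4 rose. By camera the list had adjusted p = 0.045, and adjusted p = 0.56 with an estimated correlation. Olig2, a gene of somatic motor neuron progenitors, rose by 2.14 (4.71 ± 4.1 against 0.12 ± 0.0788 FPKM). SHH targets rose in 5 of 7 cases (6 adjusted over the list alone), with Ptch1 at 117 ± 34.8 against 31.1 ± 3.55 FPKM and Mycn at 20.3 ± 8.12 against 4.24 ± 1.35 FPKM. Their camera adjusted p was 0.00164, and adjusted p = 0.156 with an estimated correlation. The Notch ligand genes Dll1 and Jag1 rose by 2.45 (155 ± 5.45 against 28.1 ± 6.51 FPKM) and 2.40, and the gliogenic genes Sox9 and Sox8 by 2.52 and 3.11. Cell cycle genes rose in 21 of 25 cases (23 adjusted over the list alone), such as Mki67 (49.3 ± 19.5 against 18.7 ± 2.7 FPKM) and Mcm7 (118 ± 67 against 38.9 ± 3.52 FPKM). Camera gave the list adjusted p = 2.28e-08, and adjusted p = 0.529 with an estimated correlation. TGF-beta genes fell in 7 of 9 cases, with Tgfbr2 at 2.1 ± 1.16 against 21 ± 3.35 FPKM. As a list they had a camera adjusted p of 7.66e-04, and adjusted p = 0.0357 with an estimated correlation. The ephrin gene Efnb3 fell by 3.09 while the ephrin receptor gene Ephb1 rose by 2.46. Nrp2 fell by 3.13, and the monoamine transporter gene Slc18a2 and the catecholamine enzyme gene Th fell by 2.65 and 2.72. Acta2, higher in the mutant on day 1, fell by 3.65 (3.39 ± 0.607 against 57.5 ± 27.5 FPKM), and the mesenchymal gene Twist1 fell by 2.71. Pou5f1 (13 ± 9.32 against 0.705 ± 0.25 FPKM), Apoe (75.2 ± 60.9 against 4.94 ± 0.9 FPKM) and Epcam (8.76 ± 3.21 against 1.89 ± 0.873 FPKM) were higher again, as were Cyp26b1 by 4.68 and Grb10 by 4.75. The mutant libraries of equal number on days 6.5 and 7.5 deviated together (correlation 0.538). The calls of these days are therefore not separate evidence. There were 4411 called genes, 2336 higher and 2075 lower, against 2341 without Foxa2-/- replicate 1, of which 41.7% were higher, and 48.4% were higher without WT replicate 3. Mki67 lost its call without Foxa2-/- replicate 1 (0.90) and Olig2 without Foxa2-/- replicate 2 (1.33). With only the groups compared 2015 genes were called, 39.5% of them higher in place of 53%. The calls of Nkx6-2, Olig2, Isl1, Mki67, Mcm7, Th and Epcam ended there.

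**Figure D2:**
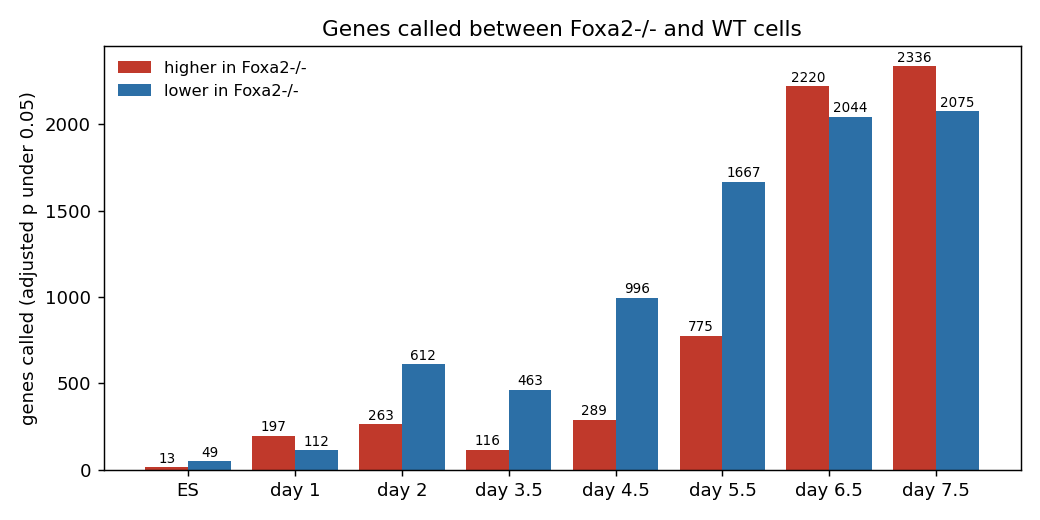
Number of genes called higher (red) and lower (blue) in Foxa2-/- than in WT cells at each of the 8 times, among 16465 genes tested up to day 2 and 17124 later. Lower genes outnumber higher ones from day 2 to day 5.5, for instance 1667 against 775 on day 5.5, and the numbers are close on day 7.5, with 2075 and 2336; the split on day 5.5 becomes 1304 and 1396 with the length trend removed.

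**Figure D3:**
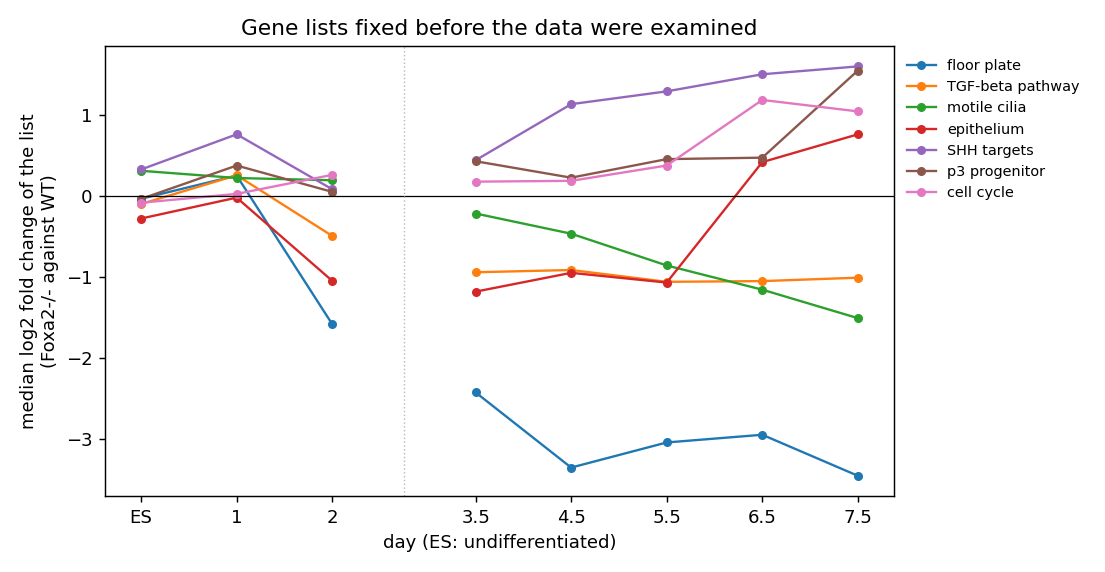
Median log2 fold change (Foxa2-/- against WT) of 7 gene lists at each day, with a dotted line between the 2 tables. The floor plate list falls to -1.59 on day 2 and -3.46 on day 7.5 and the SHH targets reach 1.60 on day 7.5; under other scalings the medians of the p3 list in undifferentiated cells and on day 2, and of the cell cycle list on days 1 and 2, change sign.

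The change from undifferentiated cells to day 2 addresses how far each genotype left pluripotency before sorting. In WT cells the pluripotency genes Tdgf1, Pou5f1 and Nanog fell by 7.62, 6.52 and 5.92, with Pou5f1 at 8.33 ± 2 FPKM on day 2 against 895 ± 425 before (SD, n = 2 each). In Foxa2-/- cells they fell by 7.80, 5.97 and 6.10 (Pou5f1 12 ± 3.63 against 831 ± 297 FPKM, n = 3 each). In both genotypes 19 of 20 naive genes fell (camera adjusted p = 5.20e-20 and 5.88e-17, and adjusted p = 0.0186 and 0.0313 with an estimated correlation). Retinoic acid response genes rose in 13 of 14 cases in each genotype (camera adjusted p = 3.89e-10 in WT and 5.54e-08 in Foxa2-/- cells, and adjusted p = 0.0686 and 0.162 with an estimated correlation). The retinoic acid-binding gene Crabp1 rose by 4.71 in WT and 6.60 in Foxa2-/- cells. The retinol transporter gene Stra6 rose by 4.98 in WT cells, and Crabp2 by 6.45 in the mutant. Neural progenitor genes rose in 14 of 17 cases in WT and 13 in mutant cells (camera adjusted p = 1.34e-07 and 2.77e-07, and adjusted p = 0.0292 and 0.0313 with an estimated correlation). Hoxd3, which marks posterior identity, rose by 3.77 and 5.16. In WT cells Foxa2 rose by 4.37, Shh by 3.54, Ptch1 by 4.07, Gli1 by 3.17, Igfbp5 by 6.12 and the arginase gene Arg1 by 5.04. Floor plate genes rose in 12 of 13 cases in WT cells. The camera test gave adjusted p = 6.12e-10, and adjusted p = 0.066 with an estimated correlation. In the mutant 10 rose and 1 fell. Together they had a camera adjusted p of 0.00656, and adjusted p = 0.311 with an estimated correlation. The Notch ligand gene Dll1 rose by 2.60 in the mutant, where 11 of 11 proneural and Notch genes rose. For this list camera gave adjusted p = 2.04e-05, and adjusted p = 0.0563 with an estimated correlation. The test of the difference between these changes (interaction) called 166 genes, 43 with a more positive and 123 with a more negative change in the mutant. Foxa2 differed by -4.36, Shh by -3.42, Vtn by -3.73, Igfbp5 by -3.27, Cdh1 by -2.48 and Crabp2 by 2.22. Of 13 floor plate genes 5 had a more negative change in the mutant (10 adjusted over the list alone). Tested as a list, they had camera adjusted p = 9.25e-12, and adjusted p = 0.105 with an estimated correlation. Called genes numbered 5582 in WT cells (3143 higher and 2439 lower on day 2; 3569 without undifferentiated WT replicate 2 and 3596 without day 2 WT replicate 2). In Foxa2-/- cells they numbered 8989 (5163 and 3826), or 5787 without both steep libraries and 14717 with array weights. With quantile normalization 45.8% of the called genes were higher on day 2 in WT cells in place of 56.3%. The median of all genes shifted by -0.188 (-0.115 with median-of-ratios), with shifts of -0.123 and -0.155 in the mutant. The excess of higher genes in the mutant depended on the scaling. Median-of-ratios factors gave 4280 higher and 4635 lower genes there, quantile normalization 4471 and 4423, and removal of the length trend 4632 and 4579. The interaction count rested on single libraries. It was 82 and 100 without undifferentiated WT replicates 1 and 2, 54 and 98 without those of day 2. It was 68, 104 and 67 without undifferentiated Foxa2-/- replicates 1, 2 and 3, and 3984 and 80 without day 2 Foxa2-/- replicates 2 and 3. Without both steep libraries it was 90, with only the groups compared 45, where Crabp2 lost its call, and 92 with quantile normalization, where 38% were higher in place of 25.9%. A pseudocount of 0.1 gave 75, a replicate block 61, no filter 320, isolated zeros as missing 407 and array weights 5716 (48% higher).

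The change from day 3.5 to day 7.5 addresses how the sorted cells changed with time in each genotype. Retinoic acid was given up to day 3.5 only, so an effect of its end is not separated from one of time. Floor plate genes rose further in WT cells. Corin rose by 5.61 (282 ± 42.6 FPKM on day 7.5 against 4.77 ± 0.847 on day 3.5, SD, n = 3 each). Foxj1 rose by 3.92, the potassium channel subunit gene Dpp6 by 4.88 and Shh by 1.88. All 17 floor plate genes tested rose. In the camera test the list had adjusted p = 5.64e-11, and adjusted p = 0.229 with an estimated correlation. Of 16 motile cilia genes 13 rose and 1 fell. Tested with camera, these genes had adjusted p = 1.84e-06, and adjusted p = 0.229 with an estimated correlation. The mitotic genes Top2a and Mki67 fell by 1.97 and 1.94 and the cyclin gene Ccne1 by 3.18. All 25 cell cycle genes fell. This list had a camera adjusted p of 1.73e-16, and adjusted p = 0.229 with an estimated correlation. Also lower on day 7.5 in WT cells were Gli1 by 2.96, Olig2 by 3.71, the motor neuron gene Lhx3 by 1.60, the neurogenic gene Neurod4 by 4.46 and Crabp1 by 4.86. Of 7 SHH targets 6 fell. These genes had a camera adjusted p of 0.00379, and adjusted p = 0.229 with an estimated correlation. Of 8 genes of somatic motor neurons 6 fell. By camera the list had adjusted p = 0.00981, and adjusted p = 0.618 with an estimated correlation. Slc18a2, the gliogenic gene Nfia and the astrocyte enzyme gene Aldh1l1 rose by 4.42, 3.28 and 3.33. In Foxa2-/- cells Aldh1l1 rose by 4.98 (57.4 ± 3.41 against 0.965 ± 0.754 FPKM, n = 2 and 3). The lysophospholipase gene Enpp2 rose by 6.41 and the radial glial phosphatase gene Ptprz1 by 5.12, with 7 of 10 glial genes higher. Their camera adjusted p was 6.19e-05, and adjusted p = 0.15 with an estimated correlation. Pax6 and Crabp1 fell by 3.80 and 4.70. Mki67 fell by 0.91 (49.3 ± 19.5 against 89.8 ± 8.05 FPKM, adjusted p = 0.0204), with 23 of 25 cell cycle genes lower. Camera gave the list adjusted p = 1.77e-12, and adjusted p = 0.286 with an estimated correlation. Epcam and Cdh1 rose by 2.62 and 2.38, and 8 of 8 epithelial genes rose. As a list they had a camera adjusted p of 4.76e-05, and adjusted p = 0.15 with an estimated correlation. Neuronal genes rose in 13 of 23 cases in the mutant. The camera test gave adjusted p = 0.0149, and adjusted p = 0.682 with an estimated correlation. The interaction called 1270 genes, 635 in each direction, but 40% were higher with quantile normalization (607 and 909), 43.8% with median-of-ratios factors and 44.4% with the length trend removed, and 63.1% without day 7.5 Foxa2-/- replicate 2 (810 and 473), and array weights called 2140. The change was more negative in the mutant for Corin (-5.67), the prodynorphin gene Pdyn (-4.78), Foxj1 (-2.98) and Tekt4 (-2.04). It was more positive for Isl1 (3.19), Cdh1 (3.16), Epcam (2.47), Dll1 (2.35), Jag1 (2.32), Nkx2-2 (2.23) and Ptch1 (1.42). Of 17 floor plate genes 9 had a more negative change in the mutant (11 adjusted over the list alone). Together they had a camera adjusted p of 7.24e-11, and adjusted p = 0.109 with an estimated correlation. Motile cilia genes did so in 10 of 16 cases. For this list camera gave adjusted p = 8.23e-09, and adjusted p = 0.109 with an estimated correlation. The difference was upward for 4 of 8 epithelial genes. Tested as a list, they had camera adjusted p = 7.67e-07, and adjusted p = 0.109 with an estimated correlation. It was upward as well for 3 of 7 visceral motor neuron genes. In the camera test the list had adjusted p = 8.56e-05, and adjusted p = 0.364 with an estimated correlation. Of 7 SHH targets 2 had a more positive change. Tested with camera, these genes had adjusted p = 0.0159, and adjusted p = 0.421 with an estimated correlation. WT cells had 8019 called genes (4189 higher and 3830 lower on day 7.5; 38.4% higher in place of 52.2% with the length trend removed, median shift -0.172). Foxa2-/- cells had 5498 (3203 and 2295; 42.4% higher in place of 58.3% with quantile normalization, shift -0.164, and 35.5% with the length trend removed, shift -0.196). The mutant count was 1651 without day 7.5 replicate 2 and 660 with only the groups compared, 94.1% of them higher, and 3543 with array weights. Mki67 lost its call without day 3.5 replicate 3 (-0.84), without day 7.5 replicate 2 (-0.50), with only the groups compared and with quantile normalization.

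The Nkx2.2 arm asks which genes depend on Nkx2.2 in cells that received SAG for the first 3.5 days. It has 1 library per group, so its differences are values without a test or an error. Nkx2-2 itself stood at 19.6 FPKM in WT and 1.34 in Nkx2.2-/- cells on day 3.5 and at 28.7 and 3.38 on day 5.5. Foxa2 remained expressed, at 171 and 160 FPKM on day 3.5 and 259 and 240 on day 5.5, and so did Shh (142 and 176, then 403 and 427). Other floor plate genes were lower in the mutant on day 5.5, with Corin at 18.8 against 62.6 FPKM, Ferd3l at 43.3 against 79.7 and Spon1 at 209 against 322. The median log2 difference of 17 floor plate genes was -0.31 on day 5.5, 15 of them lower, below all of 10000 random lists of the same size and expression (percentile 0), and -0.04 on day 3.5 (percentile 25.2). Nkx2-9, the close relative of Nkx2-2, was higher on both days, by 1.11 on the log2 scale and then 1.90 (50.8 against 12.9 FPKM), and Nkx6-2 at 107 against 50.4 and 52.3 against 30.1. Pax6 was at 18.9 and 18.7 FPKM on day 3.5 and at 15.5 in the mutant against 1.95 in WT cells on day 5.5. SHH targets were higher on day 5.5, with Ptch1 at 234 against 122 FPKM, Gli1 at 10.6 against 3.99 and Hhip at 8.93 against 2.87. The median of the 7 targets was 0.94 on day 5.5, 5 of them higher (percentile 100), and -0.15 on day 3.5 (percentile 9.22). With no filter the medians were 0.579 and -0.091 over 8 targets. Epithelial genes were lower on both days, with Cdh1 at 8.72 against 32.1 FPKM and at 2.83 against 12.8, the keratin gene Krt18 at 66.8 against 185 and at 26.9 against 91.9. The list had medians of -1.30 and -0.88 over 7 genes, 7 of them lower on both days (percentile 0 on both), and of -0.452 and -0.479 over 14 genes with no filter, 14 and 12 of them lower. Olig2 was at 2.53 against 0.42 FPKM on day 5.5. Some of the largest differences among protein-coding genes were much the same on both days. Rps2 stood at 23.1 FPKM in the mutant against 254 in WT cells on day 3.5 and at 14.3 against 212 on day 5.5, Mid1 at 83.7 against 665 and 66.5 against 492, and Rpl29 at 146 against 7.85 and 124 against 7.77. The imprinted gene Meg3 was at 50.8 against 156 and 37.3 against 278, and 21 imprinted genes had medians of -0.16 (percentile 0.26) and -0.24 (percentile 0.02). On day 5.5 stress and p53 target genes were lower too, with medians of -0.28 and -0.26 (percentiles 0.02 and 0.1), so the floor plate and SHH target lists were not alone at the extremes. With 1 library per group a difference between lines or libraries is not separated from one of genotype. The random lists draw their genes independently, so lists whose genes vary together reach extreme percentiles more easily. The stage field of the libraries titled day 5.5 reads 3.5 days.

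**Figure D4:**
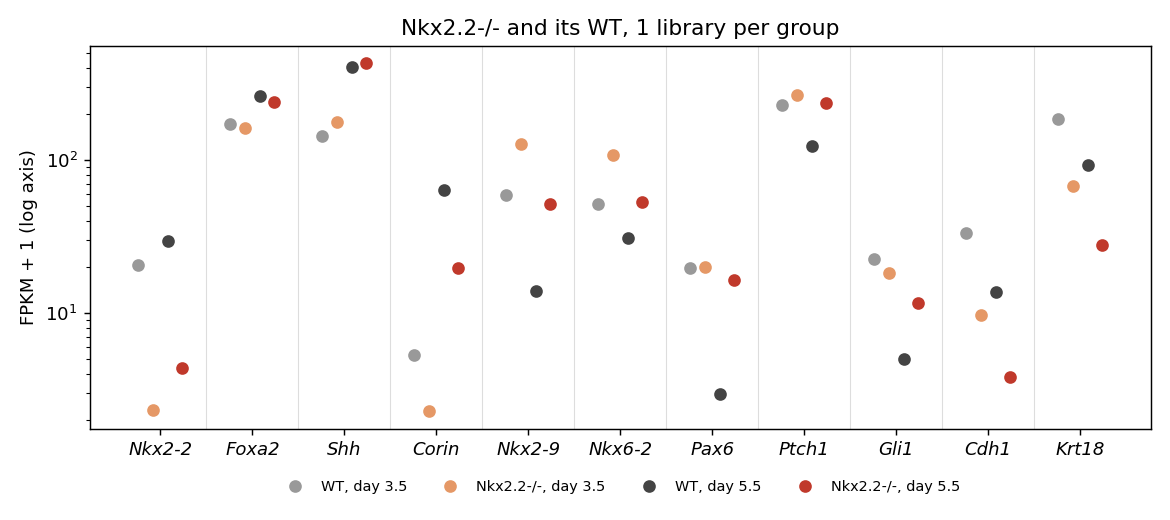
FPKM + 1 (log axis) of 11 genes in the 4 libraries of the Nkx2.2 arm, 1 point per library, with WT in light (day 3.5) and dark grey (day 5.5) and Nkx2.2-/- in orange and red. On day 5.5 Pax6 stands at 15.5 FPKM in the mutant against 1.95 in WT cells and Ptch1 at 234 against 122, while Foxa2 stands at 240 against 259.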

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

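The bounds of the day 2 tests were set before their values were seen, but both tests use settings chosen after the length trends of the libraries were seen, and the tests on SHH targets and on Pou5f1 were chosen after the result.

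The change from undifferentiated cells to day 2 differed between the genotypes for 166 genes in the test of the interaction, a count that ranged from 54 to 3984 when 1 library was left out and was 61 with a replicate block and 45 with only the groups compared, where Crabp2 lost its call. Among them Foxa2 (-4.36), the floor plate signal Shh (-3.42), Vtn (-3.73), Igfbp5 (-3.27) and Cdh1 (-2.48) had a more negative change in Foxa2-/- cells, and the retinoic acid-binding gene Crabp2 (2.22) a more positive one. The change from day 3.5 to day 7.5 differed for 1270 genes, 860 to 1283 when 1 library was left out. More negative in Foxa2-/- cells were the floor plate gene Corin (-5.67), Pdyn (-4.78) and the cilia genes Foxj1 (-2.98) and Tekt4 (-2.04). More positive were Isl1 (3.19), the Notch ligand genes Dll1 (2.35) and Jag1 (2.32), the epithelial genes Cdh1 (3.16) and Epcam (2.47), Ptch1 (1.42) and Nkx2-2 (2.23).

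On day 2 more genes were lower (612) than higher (263) in Foxa2-/- cells, and 2 of the 3 mutant libraries had few reads on long transcripts. Without both of these libraries the share of lower genes met the bound set against them as the source of the excess. Only a single mutant library is left in that fit, with its spread taken from other groups, so the fit cannot decide this. With the length trend of each library removed 55.7% of the called genes were lower in place of 69.9%, between the bounds set for and against a length trend, so part of the excess may follow transcript length. With quantile normalization 280 genes were higher and 351 lower (55.6%), with a median shift of 0.126, so part of it may also follow the scaling. A biological excess of lower genes stays open, and the line label differs with the genotype.

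As a list, SHH target genes were called higher in Foxa2-/- cells by camera with its preset correlation at every time except day 2, by fry on day 1 and from day 4.5 on, and at no time with an estimated correlation (adjusted p = 0.0686 at the lowest, on day 5.5). The median was 1.29 on the log2 scale over 7 genes on day 5.5. The medians at earlier times were 0.32 in undifferentiated cells, 0.76 on day 1, 0.08 on day 2 and 0.44 on day 3.5. By the bounds set, a constant difference between the lines was not decided. The day 1 value is above the share of 50% of 1.29 that was asked for, while the other 3 are below it. A difference constant in time would give no change up to day 5.5. The median change was 1.13 from undifferentiated cells (2.49 times the median standard error of the targets) and 1.32 from day 2 (2.91 times). It was smaller from days 1 and 3.5, at 0.42 (0.94 times) and 0.65 (1.51 times). For the 7 targets as a set, the changes from undifferentiated cells and day 2 argue against a difference constant over all times. The changes from days 1 and 3.5 do not decide. The added 1 shrinks differences of targets that were low in undifferentiated cells, and the mutant libraries of day 2 differed in length trend. A larger share of progenitors among the sorted mutant cells stays open. The neural progenitor list had a median of 0.27 on day 5.5, but 8 of its 17 genes reached 50% of 1.29. In this list 4 genes were called higher and 2 lower. A smaller fall of the targets over time in the mutant stays open, since 2 of 7 were called higher in the interaction and 4 would have been needed. Stronger pathway activity at the same SAG and a difference between lines that appears only on differentiation also remain possible and could not be separated here.

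Pou5f1 was higher in Foxa2-/- cells on days 6.5 and 7.5, at 19.6 FPKM in replicate 1 on both days and at 5.94 and 6.37 in replicate 2. In replicate 1 a small share of cells with the profile of the undifferentiated mutant libraries is argued against: at the share that Pou5f1 gives (2.36% and 2.35%) the other naive genes reached a median of 0.104 of their expected level on both days, with Tdgf1 at 0.566 FPKM against 5.77 and Dppa5a at 4.36 against 35.7 on day 6.5. Of these 18 genes 5 were over 50% of their expected level on each day, with Nanog at 2.27 FPKM against 2.06 and Lin28a at 39.1 against 5.45 on day 6.5, so cells in another state that keep Pou5f1 and Nanog are not excluded. The mutant libraries of equal number on the 2 days deviated together (correlation 0.538), so the days are not separate evidence. In replicate 2 (0.715% and 0.767%) the medians were 1.072 and 0.451, so a small share of undifferentiated cells cannot be told apart from other sources: on day 6.5 Dppa5a stood at 39.1 against 10.8 FPKM expected, while Tdgf1 was listed at 0 against 1.75. No biological explanation was tested for the level in replicate 1.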

How the results depend on the processing

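The settings of isolated zeros as missing, length trend removed, array weights and both steep libraries left out were chosen after the data were seen. Of the 14 counts of called genes, that of WT day 7.5 against day 3.5 stayed within 1.5 times its value throughout, and none moved by more than that with median-of-ratios factors, without a variance trend or with the length trend removed. With no filter 165 genes were called in undifferentiated cells, 5.2e+02 (rounded) on day 1 and 320 in the day 2 interaction; the last became 75 with a pseudocount of 0.1 and 92 with quantile normalization. With a replicate block the counts were 21, 132, 384 and 61 for undifferentiated cells, day 1, day 2 and the day 2 interaction. The median correlation of deviations from the group means was -0.037 for libraries of equal number and 0.0285 for others up to day 2, and 0.012 and -0.009 later, so the numbers do not pair the samples throughout; the highest later values were 0.538 for equal numbers, between the mutant libraries of days 6.5 and 7.5, and 0.35 for others. With isolated zeros as missing they were 207, 510, 1316, 878 and 407 for undifferentiated cells, days 1, 2 and 3.5 and the day 2 interaction. With array weights they were 1.4e+02 (rounded) in undifferentiated cells, 813 on day 1, 10450 on day 2, 4907 on day 3.5, 2217 on day 4.5, 6267 on day 5.5 and 2675 on day 6.5, 14717 and 3543 for the mutant's changes to day 2 and from day 3.5 to 7.5, and 5716 and 2140 for the interactions. With only the groups compared, where fewer libraries estimate the spread, they were 24 in undifferentiated cells, 150 on day 1, 32 on day 2, 580 on day 4.5, 640 on day 6.5, 2015 on day 7.5, 660 for the mutant from day 3.5 to 7.5 and 45 for the day 2 interaction. Without both steep libraries they were 248 on day 2, 5787 for the mutant's change to day 2 and 90 for its interaction. Leaving out each library gave 23 to 45 in undifferentiated cells, 62 to 294 on day 1, 258 to 6039 on day 2, 341 to 450 on day 3.5, 770 to 1305 on day 4.5, 2341 to 4542 on day 7.5, 3569 to 5063 for the WT change to day 2, 1651 to 6029 for the mutant from day 3.5 to 7.5 and 54 to 3984 for the day 2 interaction. Of 204 named gene values 35 lost their call with only the groups compared, 1 with quantile normalization, 1 without both steep libraries, and leaving out 1 library ended a call in 9 cases, few because named genes were mostly chosen for calls that held there, so this is no test of stability. Of 164 list calls 144 were lost with an estimated correlation and 26 with fry. Of 62 list medians of the Nkx2.2 arm 37 moved by less than the spread of the random lists throughout and 10 changed sign. With no filter the medians of the mesoderm (0.255 to -0.066) and endoderm (0.06 to -0.125) lists on day 3.5 and of the Hox (0.179 to -0.013), visceral motor neuron (0.161 to -0.005) and formative pluripotency (0.02 to -0.016) lists on day 5.5 did so. With quantile normalization those of the motile cilia (-0.079 to 0.033) and visceral motor neuron (-0.069 to 0.006) lists on day 3.5 and of the intermediate and dorsal progenitor (-0.162 to 0.035), neural crest (-0.135 to 0.001) and SHH co-receptor (-0.004 to 0.019) lists on day 5.5 did. The causes of these moves were not tested. The fits of only the groups compared change both the number of libraries and the groups whose spread is used. Depth was estimated from the steps between low FPKM values, and how it limits the calls of low genes was not measured.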

Other observations

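The overlap with WT changes over time and the day 5.5 tests in the Nkx2.2 arm were set before the result was seen, and the look at day 3.5 in that arm was chosen after it.

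Hox genes, which mark position along the body axis, were lower in Foxa2-/- cells on day 6.5: 7 of 16 fell (13 adjusted over the list alone), among them Hoxa3, Hoxa5, Hoxb5 and Hoxb8. This list had a camera adjusted p of 2.33e-04, and adjusted p = 0.521 with an estimated correlation. Glycolysis and hypoxia genes rose on that day in 6 of 17 cases (11 adjusted over the list alone). These genes had a camera adjusted p of 0.00825, and adjusted p = 0.521 with an estimated correlation. Mesoderm markers fell in 3 of 11 cases on day 5.5 (4 adjusted over the list alone). By camera the list had adjusted p = 0.0173, and adjusted p = 0.373 with an estimated correlation. Proneural and Notch genes had a more positive change from day 3.5 to 7.5 in the mutant in 5 of 12 cases. Their camera adjusted p was 0.00262, and adjusted p = 0.437 with an estimated correlation.

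In the Nkx2.2 arm, with 1 library per group, neuronal genes had a median log2 difference of -0.60 on day 3.5, with 21 of 22 lower in the mutant (percentile 0 of the random lists), and of -0.20 on day 5.5 (percentile 1.92). Retinoic acid response genes had medians of -0.34 on day 3.5 (percentile 0.01) and -0.19 on day 5.5 (percentile 2.9, and 6.07 with no filter). Glycolysis and hypoxia genes had a median of -0.12 on day 3.5 (percentile 4.83, and 21.79 with quantile normalization) and -0.57 on day 5.5, with 16 of 18 lower (percentile 0), and motile cilia genes -0.08 (percentile 38, and a median of 0.033 with quantile normalization) and -0.37 (percentile 0.5).

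Of the 1667 genes lower in Foxa2-/- cells on day 5.5, 1236 rose in WT cells from day 3.5 to day 7.5, comparisons that share no library, where 407.8 would do so in independent lists, a ratio of 3.03; 45 fell in WT cells, where 372.8 would. Of the 775 higher genes 420 fell in WT cells, where 173.3 would. The ratio of 3.03 met what was set in advance for a mutant that lacks part of the rise of WT cells over time. Both comparisons come from the same fit and share its spread per gene, so 407.8 and the other expected numbers are not exact. Both also depend on transcript length. With the length trend removed 1304 genes were lower and 1396 higher on day 5.5. Of the called WT genes 38.4% then rose, in place of 52.2%. The overlap was not repeated in that setting, so a contribution of length was not tested.

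The genes lower in Foxa2-/- cells on day 5.5 had a median of -0.12 in Nkx2.2-/- against WT cells on day 5.5, at percentile 0 of random matched lists, and the higher genes had a median of 0.09, at percentile 100. Both values met what was set in advance for genes that the loss of Nkx2.2 lowers or raises too, but with 1 library per group they cannot be told apart from a difference between those libraries. On day 3.5 the percentiles were 51.1 and 97.3, and with quantile normalization 99.7 (median 0.022) and 88.75, so those of day 3.5 depend on the scaling. The day 5.5 percentiles stayed at 0 and 100 with quantile normalization (medians -0.085 and 0.128). The random lists were matched on mean expression but not on transcript length. The length slopes were 0.029 in the mutant and -0.014 in the WT library of day 5.5, and -0.006 and -0.008 on day 3.5. Whether transcript length adds to these percentiles was not tested. Random lists draw genes independently, so genes that vary together give extreme percentiles more easily.

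The 6 libraries of days 3.5, 4.5 and 5.5, and of the WT change from day 3.5 to 7.5, can be divided in 10 ways each, too few for a share under 0.05 of such splits; in each comparison 1 of the 10 splits, the real one, gave a count as large. The real splits gave 579, 1285, 2442 and 8019 called genes and the highest other splits 3, 2, 2 and 1. The other splits mix the genotypes, or for the WT change the days, within each group. A separation of the real groups then adds to the spread, whatever its cause, so low counts there do not argue against chance.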
